A study of Homo sapiens with 8 samples.

How the data were processed

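RNA abundance was measured in MCF7 cells, an established human breast cancer line that carries the estrogen receptor, 16 h after infection with adenovirus. The control virus expressed GFP, and the other viruses expressed GFP together with c-Myb, 3Mutc Myb or v-Myb, per the labels' protocols. c-Myb is the transcription factor encoded by the MYB proto-oncogene, and v-Myb is its oncogenic retroviral form. The 3Mutc form was known here by its label alone. Each of the 4 groups held 2 arrays, 8 in all, and the design text states that the 2 experiments of each kind were done independently and over a week apart.

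About 1 µg of total RNA per sample was turned into biotin-labelled cRNA and hybridised to a 1-colour Affymetrix array with 22283 probe sets. The authors deposited 1 value per probe set and array in units of signal intensity on a linear scale, made with MAS5 per the submitters' processing notes. The version and settings of MAS5 are not given in the sources used here. Each deposited column had a 2% trimmed mean of 500.2, so the intensities had been scaled to a common level before deposit. No detection calls were used here, so dim probe sets could be judged only by their signal. Array signals carry no counts, and the precision was limited by the number of arrays.

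Probe sets were named from the platform annotation supplied with the series, in which 19071 probe sets had 1 gene symbol, 1043 had several and 2169 had none. Probe sets with several symbols or none were tested and counted but not named. No genome build was named, so no coordinates are given. The 68 control probe sets of the array were left out. The authors' intensities were rescaled to a 2% trimmed mean of 500 on every array and transformed as log2(signal + 16). Adding 16 lowers fold changes of dim probe sets compared with the plain ratio of signals. Genes named for large fold changes can still rest on dim readings. A probe set was tested when its signal lay above its own array's median on at least 2 of the 8 arrays, which left 13464 probe sets and 8276 genes with 1 symbol.

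Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend). All 8 arrays entered 1 fit without covariates, with 4 residual degrees of freedom and a prior of 8.81, because each group alone had too few arrays to estimate a spread. Benjamini-Hochberg adjustment was applied within each of 6 comparisons, and an adjusted p under 0.05 was called. Every adjusted p for a single gene comes from this limma fit, and all tests were two-sided. The replicate arrays were independent experiments, and their spread includes both biological and technical variation.

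The sample groups, the tests, the gene lists, the rule for named genes and the alternative settings were chosen before the data were examined. Gene lists were tested with limma's camera at a preset correlation of 0.01, on the brightest probe set of each gene, and adjusted over the 18 lists with at least 5 measured genes. They covered known Myb targets, estrogen response, G1/S and DNA replication, G2/M and mitosis, interferon response, p53 targets, unfolded protein response, heat shock, NF-kB and TNF response, immediate early genes, the BCL2 family, hematopoietic markers, luminal epithelial markers, basal and mesenchymal markers, histones, cholesterol synthesis, hypoxia and glycolysis, and housekeeping genes. MYB, MYBL1 and MYBL2 were reported individually. camera was repeated with a correlation estimated from the residuals, and fry was run on the same lists. fry asks whether a list's genes move 1 way on balance and does not compare them with other genes.

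The genes named were chosen by a fixed rule. For each Myb form against control, they were the 15 largest rises and the 10 largest falls among probe sets with 1 gene symbol, an adjusted p under 0.05 and both arrays of the group beyond both control arrays. For each pair of Myb forms, they were the 8 largest in each direction by the same rule. A gene was named by its called probe set with the largest change, and its other probe sets that passed the filter are mentioned where they were not called in the same direction. Up to 4 members of each list with the largest changes could be named whether called or not. Genes outside this rule are said to be so where they appear, apart from BAIAP2 and MORF4L1, which were named after their values were seen.

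Overlaps between comparisons that share the control arrays were set beside 100 simulations of unchanged groups against those arrays and beside the product expected of independent lists. The scripts were tested on simulated data for c-Myb against control over 13464 probe sets, with 200 changed. At a log2 change of 1, 24.0% of the changed probe sets were recovered with 2 false calls, and at a log2 change of 2, 66.5% were recovered with 8 false calls. The simulated noise was independent and normal, with its spread taken from the same fit with the intensity trend. These counts therefore check the scripts and cannot check the trend, or errors that are correlated or not normal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

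The alternative settings were quantile normalization, no rescaling, pseudocounts of 1 and 64, no filter, a filter on a mean above the 60th percentile, eBayes without the trend, the replicate number as a block, a fold threshold of 2, 1 probe set per gene, a mean over each gene's probe sets for the lists, an estimated correlation in camera, fits of the compared groups alone, and leaving out each array in turn. The brightest probe set of each named gene was added after seeing the data. The replicate numbers of the labels were treated as names, because the labels do not say that a number marks a shared day.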

Results

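Gene expression was profiled in MCF7 breast cancer cells infected for 16 h with adenovirus carrying GFP alone (control) or GFP with c-Myb, 3Mutc Myb or v-Myb. The comparisons addressed which genes each Myb form changes in the same cells and where the forms differ. Each group held 2 arrays, and values below are mean signal intensity ± SD over those 2 arrays unless stated otherwise. Median signal per array lay between 176 and 216, and the median standard error of a log2 difference between 2 groups was 0.36. Pearson's r of log2 signal across probe sets, which are not independent replicates, was 0.883 between the control arrays, 0.925 between the c-Myb arrays, 0.9205 between the 3Mutc arrays and 0.895 between the v-Myb arrays. v-Myb replicate 2 correlated more closely with each c-Myb and 3Mutc array, at 0.90 to 0.906, than with v-Myb replicate 1. Control replicate 1 also correlated more closely with c-Myb replicate 1 (0.888) and both 3Mutc arrays (0.889 and 0.8875) than with control replicate 2, and 3Mutc replicate 2 with c-Myb replicate 1 (0.922) than with 3Mutc replicate 1. The geometric mean of the hybridisation spike-in probe sets was 8003 on c-Myb replicate 2 and 10290 on v-Myb replicate 2, against 14300 to 17600 on the other arrays. Signs of RNA quality also differed between groups. The 28S ribosomal RNA probe set read 791 and 1007 on the control arrays, 347 and 312 with c-Myb, 494 and 735 with 3Mutc and 438 and 423 with v-Myb. The ratio of 3' to 5' probe sets of ACTB was 0.874 and 0.906 in control cells, 0.97 and 1.06 with c-Myb, 0.968 and 0.928 with 3Mutc and 0.843 and 0.791 with v-Myb, and that of GAPDH was 1.35 on c-Myb replicate 2 and 0.968 to 1.17 on the other arrays.

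The transcript of MYB itself, which encodes c-Myb, read 414 ± 2.26 in control cells, 394 ± 119 with c-Myb, 332 ± 83.3 with 3Mutc and 403 ± 128 with v-Myb. The log2 differences from control were −0.10, −0.33 and −0.07 (limma adjusted p = 0.926, 0.741 and 0.961), and a second MYB probe set was too dim to be tested. MYBL2, a cell-cycle gene of the same family, read 1905 ± 322 in control cells and 1355 ± 207 with c-Myb, a log2 difference of −0.48 that was not called (adjusted p = 0.266). MYBL1 read 178 ± 47.1 and 175 ± 11.8 in the same groups. Whether these probe sets match the virus-borne sequences is not given in the sources used here, so their signals do not check the labels.

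With c-Myb, the largest rises were in KRT16, a keratin of stressed and rapidly dividing epithelium, and in DHRS2, a short-chain dehydrogenase/reductase. KRT16 read 4537 ± 917.7 against 115 ± 107 in control cells, a 42.1-fold difference (log2 5.40, SE 0.66, adjusted p = 0.00168). DHRS2 read 8699 ± 3982 against 204 ± 13.1, a 37.5-fold difference (log2 5.23, SE 0.28, adjusted p = 9e-07), and its other probe set rose by 4.16 log2 units. LHX6, a LIM homeobox factor, rose 7.01-fold (adjusted p = 0.0446), PPM1E, a serine/threonine phosphatase, 6.83-fold (adjusted p = 0.00501), and IL4R, a cytokine receptor chain, 5.55-fold (adjusted p = 0.0465). ISG20, an interferon-induced exonuclease, rose 9.01-fold, TRAPPC12, a vesicle-tethering subunit, 8.47-fold, the RNA-binding protein gene KHDRBS3 8.58-fold, and the efflux transporter gene ABCC3 5.77-fold. The metallothionein-like gene MT1HL1 and the Hsp70-family gene HSPA1L rose 6.40-fold and 5.36-fold. For ACAA2, SHB, SOX4 and WHRN the rise of the named probe set, 5.97-, 5.90-, 5.56- and 5.16-fold, was not shared by every other probe set. The others read −1.16 log2 units for ACAA2, 0.19 for SHB and 0.07 for WHRN, and ranged from −0.33 to 1.05 for SOX4, of which 1 was called. Either control array moved several of these folds by over 1.5 times. Without control replicates 1 and 2 the rise was 21.8- and 81.3-fold for KRT16, 4.33- and 18.7-fold for ISG20, 2.64- and 18.6-fold for LHX6, 12.6- and 3.71-fold for PPM1E and 10.1- and 4.06-fold for MT1HL1. It was 10.3- and 3.47-fold for ACAA2, 9.61- and 3.46-fold for ABCC3, 2.92- and 10.5-fold for IL4R and 3.34- and 7.96-fold for WHRN. Mean control signals ran from 24 to 66.7 for KHDRBS3, TRAPPC12, HSPA1L, SHB and SOX4. They ran from 81.2 to 204 for WHRN, ACAA2, KRT16, LHX6, IL4R, ABCC3 and DHRS2. All lay below the control arrays' median signals of 208 and 216. Without detection calls it could not be judged whether these transcripts were expressed in control cells.

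Among the named falls with c-Myb, MC2R, the corticotropin receptor, read 56.4 ± 47.1 against 479 ± 90.2 (7.64-fold lower, adjusted p = 0.0353), or 12.6- and 4.65-fold lower without c-Myb replicates 1 and 2. CAV3, a muscle caveolin, read 62.5 ± 5.3 against 494 ± 163.1 (6.33-fold lower). PRPH2 of photoreceptors, the odorant receptor gene OR12D2 and SYT1, a synaptic vesicle protein gene, were 5.01-, 4.82- and 2.77-fold lower. The mean c-Myb signals of MC2R, CAV3, PRPH2 and OR12D2, from 56.4 to 134, lay below the c-Myb arrays' median signals of 176 and 180. So did those of PADI1, WNT10B, YLPM1 and NTRK3, described next, from 51.6 to 100.3. Without detection calls it could not be judged whether these transcripts were expressed in either group. PADI1, a peptidylarginine deiminase of skin, fell from 595 ± 71.6 to 83.2 (6.14-fold lower, adjusted p = 0.00539), and the Wnt ligand gene WNT10B was 4.11-fold lower. The falls of YLPM1, NTRK3 and FOLR1 (5.50-, 4.54- and 3.15-fold) were not shared by all their probe sets. The other FOLR1 probe set read 1.13 log2 units higher, the others of YLPM1 read 0.09 and 0.03, and the others of NTRK3 ranged from −1.06 to 0.23.

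Among the fixed lists, 5 passed the preset-correlation test with c-Myb. In the estrogen response list 2 of 21 measured genes rose, the growth-factor-binding gene IGFBP4 (log2 1.56, adjusted p = 0.000983) and OLFM1 (0.96, adjusted p = 0.0435), and none fell. Adjusted over the list alone, 9 rose and 1 fell. GREB1, a classical estrogen-induced gene, read 1.37 log2 units higher without passing (adjusted p = 0.0852). The list had an adjusted p of 0.00193, and an adjusted p of 0.535 with an estimated correlation. In the heat shock list 3 of 13 genes rose (HSPA1L, the small chaperone gene HSPB1 at 1.06, and HSPH1 at 0.68) and SERPINH1, a collagen chaperone gene, fell by 0.75 log2 units. The counts were the same adjusted over the list alone, and the list's adjusted p was 0.00449, or an adjusted p of 0.535 with an estimated correlation. All 9 measured histone genes had positive differences with a median of 0.39. None passed over all genes, 3 rose adjusted over the list alone, and the list's adjusted p was 0.00295, or an adjusted p of 0.535 with an estimated correlation. Of 18 hypoxia and glycolysis genes, HK2, a hexokinase, rose (log2 1.95, adjusted p = 0.0359), with 4 risen adjusted over the list alone. The hypoxia list's adjusted p was 0.035, or an adjusted p of 0.613 with an estimated correlation. The G2/M and mitosis list lay lower, with a median of −0.29, and BUB1B and HMMR read −0.94 and −0.84. None of its 25 genes passed over all genes or adjusted over the list alone. Its adjusted p was 0.0186, or an adjusted p of 0.613 with an estimated correlation.

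In all, limma called 253 of 13464 probe sets with c-Myb, 197 higher and 56 lower. The arrays of both groups did not overlap for 46.7% of probe sets, against 33.3% by chance. Without the intensity trend in eBayes 2 probe sets were called, both of DHRS2 (adjusted p = 0.0278 and 0.0434). The count was 198 without control replicate 1, 180 of them higher, 124 without control replicate 2, 121 of them higher, 112 and 44 without c-Myb replicates 1 and 2, with 70 and 40 higher, and 151 and 152 without 3Mutc replicates 1 and 2, with 130 higher in each, KRT16 and DHRS2 held in each leave-out while the other 23 named genes missed the threshold in at least 1, and all 5 lists were lost without control replicate 2 (adjusted p from 0.0501 to 0.527), with G2/M, heat shock and hypoxia also lost without c-Myb replicate 1 (adjusted p = 0.254, 0.0771 and 0.47).

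**Figure D1:**
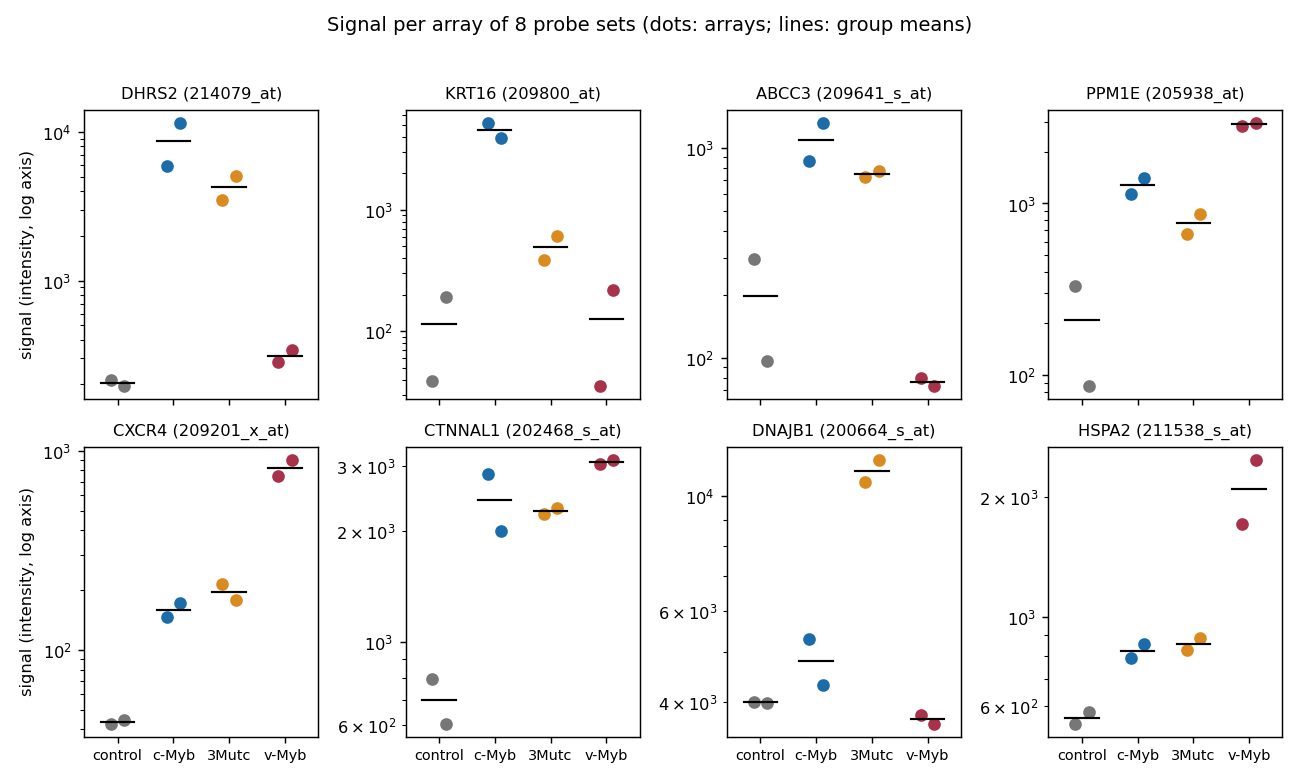
Signal intensity on a log axis for 8 probe sets on each of the 8 arrays, grouped by virus, with a dot per array and a line at each group's mean of 2 arrays. DHRS2 averaged 8699 with c-Myb, 4269 with 3Mutc, 313 with v-Myb and 204 in control cells, whereas CXCR4 averaged 825 with v-Myb and 43.8 in control cells.

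With v-Myb, the largest rises were in PPM1E and in CXCR4, the receptor for the chemokine CXCL12. PPM1E read 2898 ± 77.1 against 208 ± 172.7 in control cells, a 15.5-fold difference (log2 3.96, SE 0.41, adjusted p = 0.00124) that was 28.6- and 8.42-fold without control replicates 1 and 2. CXCR4 read 825 ± 107.4 against 43.8 ± 1.5, a 14.0-fold difference (log2 3.81, SE 0.49, adjusted p = 0.00466), and its other probe sets rose by 2.02 and 2.79 log2 units. TRAPPC12 rose 9.78-fold and CA8, a carbonic anhydrase-related gene, 7.43-fold (adjusted p = 0.0144 and 0.00346). CTNNAL1, an alpha-catenin relative, rose 4.34-fold, the kinase gene STK17A 4.25-fold, the fatty acid-binding protein gene FABP5 4.21-fold and HSPA2, an Hsp70-family gene, 3.61-fold. EZH2, the histone methyltransferase of Polycomb complexes, rose 3.19-fold (adjusted p = 0.0261), as did KLHDC2, a ubiquitin ligase subunit gene (adjusted p = 0.00124). NUCB2, GFOD1, MGAT2, an N-glycan synthesis enzyme, and EPB41L4B rose 4.25-, 3.64-, 3.51- and 3.13-fold. TEAD4, a Hippo pathway transcription factor, rose 3.40-fold on the named probe set and read 0.09 log2 units on the other, and the other STK17A probe set read 1.12 without being called. Mean control signals of TRAPPC12, CXCR4, CA8 and TEAD4, from 32.7 to 174.5, lay below the control arrays' medians of 208 and 216.

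The largest named fall with v-Myb was in PIK3C2B, a phosphoinositide kinase gene, which was 4.36-fold lower (adjusted p = 0.0461), and TNFRSF21, a death receptor, read 516 ± 139.3 against 1558 ± 518.3 (2.93-fold lower, adjusted p = 0.0251). AQP3, an aquaporin that also carries glycerol, the membrane protein gene STOM, the kynureninase gene KYNU and the calcium-binding protein gene S100A6 were 2.27-, 2.10-, 1.98- and 1.86-fold lower. ARMCX6, TRIM16 and TRIP6, a focal adhesion gene, were 2.20-, 2.07- and 2.03-fold lower. SIPA1L3 was 3.75-fold lower on the named probe set and read 1.60 log2 units higher on the other. The other probe sets of TNFRSF21, STOM, AQP3 and KYNU read lower without being called, at −0.38 and −0.49 for the first pair and between −0.36 and −1.26 for the rest.

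In total, limma called 59 probe sets with v-Myb, 45 higher and 14 lower, and groups did not overlap for 41.3% of probe sets against 33.3% by chance. By camera 0 of the 18 lists passed, with 2 at an unadjusted p under 0.05, and fry called 0, also with 2 at an unadjusted p under 0.05. The lowest adjusted p, 0.0955, was shared by G1/S and DNA replication (median 0.16, upward) and luminal epithelial markers (median −0.19, downward), and the luminal list passed without v-Myb replicate 1 (adjusted p = 0.044). Without the intensity trend 1 probe set, that of CXCR4, was called (adjusted p = 0.02). The balance turned without v-Myb replicate 2, with 11 higher and 27 lower, and the split was 15 and 12 without v-Myb replicate 1, while the count was 79 and 58 without control replicates 1 and 2, with 74 and 52 higher, 30 without either c-Myb array, 25 of them higher, and 13 and 16, all higher, without 3Mutc replicates 1 and 2, and CXCR4 missed the threshold without v-Myb replicate 1 or 2 (adjusted p = 0.0675 and 0.0885, from 0.00242 to 0.0885 over its alternatives), while PPM1E, CA8, CTNNAL1, STK17A, FABP5, HSPA2, KLHDC2 and EPB41L4B, 8 of the 25 named genes, held in each leave-out.

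With 3Mutc, DHRS2 had the largest rise, at 4269 ± 1145 against 204 ± 13.1 in control cells, a 19.1-fold difference (log2 4.26, SE 0.28, adjusted p = 8.37e-06). HSPA1L rose 8.61-fold (442 ± 161.1 against 37.0 ± 17.5, adjusted p = 0.0153), TRAPPC12 6.74-fold and CA8 6.72-fold. JAG1, a Notch ligand, rose 4.26-fold (adjusted p = 0.0485), CBR3, a carbonyl reductase, 4.07-fold (adjusted p = 0.00655) and SAP30, a subunit of a histone deacetylase complex, 3.64-fold. SAT1, which acetylates polyamines, rose on all 3 of its probe sets, at 1.74, 1.23 and 1.68 log2 units. The metallothionein genes MT1HL1 and MT1H rose 4.19-fold and 3.24-fold, and CRTAC1, PPM1E and CTNNAL1 rose 4.43-, 4.12- and 3.22-fold. Without control replicates 1 and 2 the difference was 7.59- and 2.24-fold for PPM1E, 6.60- and 2.66-fold for MT1HL1 and 9.03- and 3.06-fold for ACAA2. CRIM1 and ACAA2 rose 6.27- and 5.25-fold on the named probe sets and read 0.14 and −0.78 log2 units on the others. JAG1's others read −0.11 and 1.23, and SAP30's read 1.28 and 0.20, none of them called. Mean control signals of TRAPPC12, HSPA1L, CRIM1, CRTAC1, JAG1, CA8, ACAA2 and DHRS2 ran from 32.7 to 204. They lay below the control arrays' medians of 208 and 216.

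FOSL1, a subunit of the AP-1 transcription factor, had the largest named fall with 3Mutc, from 572 ± 221 to 121 ± 60.7 (4.35-fold lower, adjusted p = 0.0256). TFAP4, another transcription factor gene, was 4.27-fold lower, TYK2, a Janus kinase of cytokine receptors, 3.61-fold lower and DUSP14, a phosphatase of mitogen-activated kinases, 2.28-fold lower. TNFRSF12A, the TWEAK receptor, and TNFRSF10C, a decoy receptor for TRAIL, were 2.13- and 3.33-fold lower. GOLGA3, SYT1, SFXN1, a mitochondrial serine transporter gene, and SUPT6H were 3.38-, 2.76-, 2.54- and 2.41-fold lower. Other probe sets of TNFRSF10C (−2.29 log2 units) and SUPT6H (−0.36 and −0.26) were not called.

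In the heat shock list with 3Mutc, HSPA1L, HSPH1 (log2 1.57, adjusted p = 0.000178) and DNAJB1, a co-chaperone of Hsp70 proteins (1.36, adjusted p = 0.000178), were among 5 of 13 members that rose, none fell, and 11 rose and 1 fell adjusted over the list alone. The median was 0.63 and the list's adjusted p 8.05e-12, or an adjusted p of 0.150 with an estimated correlation, and fry gave an adjusted p of 0.0106. All 9 histone genes had positive differences, with a median of 0.53. The histone rise with c-Myb was measured against the same control arrays, so this is no independent repeat of it. None rose over all genes and 5 rose adjusted over the list alone, with a list adjusted p of 8.34e-05 and an adjusted p of 0.306 with an estimated correlation. Of the 16 measured p53 targets, CDKN1A, a cell-cycle inhibitor, fell by 0.76 log2 units (adjusted p = 0.0485), GDF15 read −0.91 without passing (adjusted p = 0.068), and 3 fell and 1 rose adjusted over the list alone. The p53 list's adjusted p was 0.0157, or an adjusted p of 0.288 with an estimated correlation. In the estrogen response list IGFBP4 rose (1.02, adjusted p = 0.0192), with 2 of 21 risen adjusted over the list alone, a list adjusted p of 0.0308 and an adjusted p of 0.555 with an estimated correlation.

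In total, limma called 130 probe sets with 3Mutc, 101 higher and 29 lower, and groups did not overlap for 45.4% of probe sets against 33.3% by chance. Without the intensity trend 0 were called by limma, with 1516 at an unadjusted p under 0.05 against 1781 with the trend. The count was 146 without control replicate 1, 129 of them higher, 46, all higher, without control replicate 2, 31 and 18 without 3Mutc replicates 1 and 2, with 24 and 13 higher, 85 without either c-Myb array, with 12 and 13 lower without replicates 1 and 2, and 93 and 91 without v-Myb replicates 1 and 2, with 19 lower in each, DHRS2 and CTNNAL1 alone of 25 named genes held in each leave-out, and of the lists estrogen response was lost without control replicate 2 or 3Mutc replicate 2 (adjusted p = 0.353 and 0.12) and p53 targets without 3Mutc replicate 2 (adjusted p = 0.113).

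**Figure D2:**
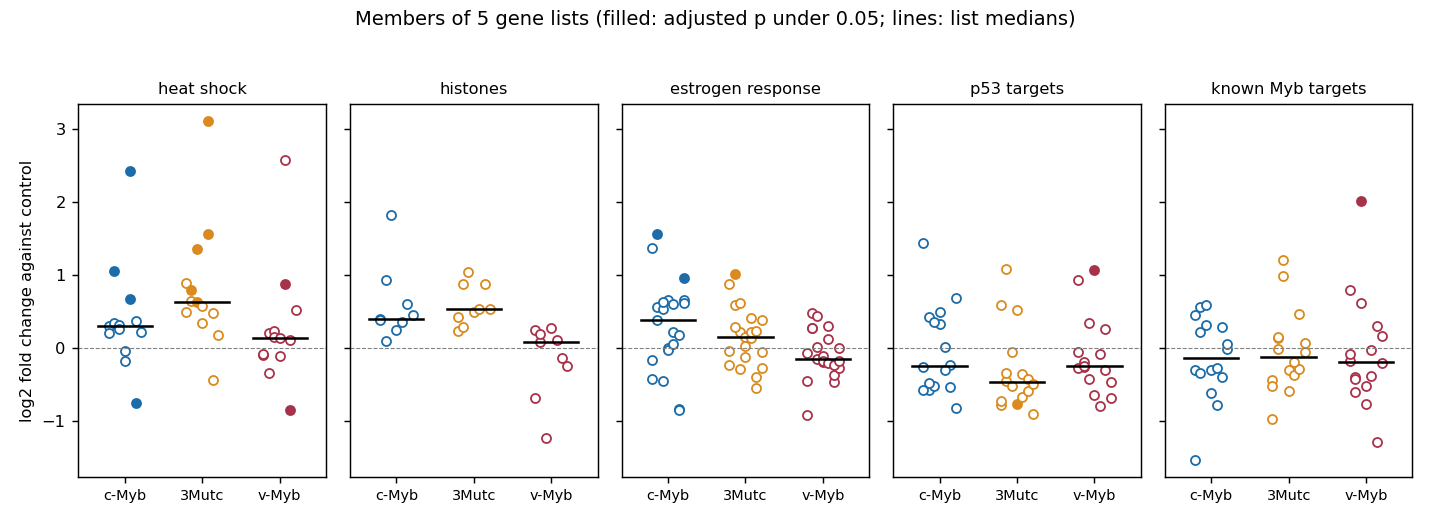
Log2 fold change against control for each measured member of 5 gene lists, by Myb form, with a circle per gene, filled where the adjusted p was under 0.05, and a line at each list's median. The heat shock median was 0.30 with c-Myb, 0.63 with 3Mutc and 0.13 with v-Myb, and the median of known Myb targets was −0.14, −0.12 and −0.19.

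The 3 Myb forms shared a set of calls against the same 2 control arrays. TRAPPC12, PPM1E, CA8, CBR3, CTNNAL1, STK17A, KLHDC2, EPB41L4B and HSPH1 were among 15 probe sets called higher with all 3 forms, and TRIM16 was lower with all 3 (log2 −0.99 with c-Myb, −1.03 with 3Mutc and −1.05 with v-Myb). The linker histone gene H1-10, the RNA-binding protein gene RBM47, the adhesion gene ALCAM, the kinase gene MAPKAPK2, RTN4 and RETREG2 completed the 15 and are named here after their values were seen. c-Myb and 3Mutc shared 74 calls in the same direction, 68 higher and 6 lower, c-Myb and v-Myb shared 25 (21 and 4) and 3Mutc and v-Myb shared 20 (19 and 1), with 0 in opposite directions. Unchanged groups simulated against the same controls shared at most 1 in any of 100 simulations. Such groups have almost no calls to share, so this count cannot show how many shared calls come from the shared controls. Independent lists would share 1.48 higher and 0.121 lower for c-Myb and 3Mutc, 0.658 and 0.0582 for c-Myb and v-Myb, and 0.338 and 0.0302 for 3Mutc and v-Myb. Fold changes correlated across probe sets at r = 0.653, 0.557 and 0.578 for these pairs, against 0.498, 0.499 and 0.501 simulated. The covariance exceeded the simulated one by 0.154, 0.116 and 0.110. The simulations gave every group the same spread at each probe set. The SD of the difference between replicate arrays was 0.831 in control cells, 0.682 with c-Myb, 0.694 with 3Mutc and 0.789 with v-Myb. Part of the excess in r and covariance may therefore come from the control arrays. With 2 control arrays no split left at least 2 in each part, so some of the excess in shared calls may come from the shared controls. No call was shared without the intensity trend, and c-Myb and 3Mutc shared 33 calls without control replicate 2, 30 and 27 without c-Myb replicates 1 and 2, and 13 and 9 without 3Mutc replicates 1 and 2. The counts for c-Myb with v-Myb and for 3Mutc with v-Myb were 55 and 53 without control replicate 1, 9 and 10 without c-Myb replicate 1, 4 and 9 without c-Myb replicate 2, 8 and 2 without 3Mutc replicate 1, 9 and 3 without 3Mutc replicate 2, 11 and 8 without v-Myb replicate 1, and 9 and 6 without v-Myb replicate 2.

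Direct comparison of v-Myb with c-Myb showed its largest named differences in KRT16 and DHRS2, which also had the largest rises with c-Myb. Both comparisons used the same c-Myb arrays, so part of this agreement is built in. The rises of TRAPPC12 and PPM1E, also among the largest with c-Myb (3.08 and 2.77 log2 units), were 3.29 and 3.96 with v-Myb. KRT16 read 127 ± 129.5 with v-Myb against 4537 ± 917.7 with c-Myb (log2 −5.36, SE 0.66, adjusted p = 0.0029), and DHRS2 read 313 ± 42.0 against 8699 ± 3982 (log2 −4.66, SE 0.28, adjusted p = 3.77e-06). ABCC3 and MT1H were 11.7- and 6.22-fold lower with v-Myb (adjusted p = 0.00365 for each). Without v-Myb replicates 1 and 2 the difference was 19.2- and 87.7-fold for KRT16, 4.02- and 9.62-fold for MT1H and 4.73- and 11.3-fold for PADI1. The AP-1 subunit gene FOSL2, the vitamin D receptor gene VDR, NAB2, a co-repressor of EGR factors, and SMAD3 of the TGF-beta pathway were 7.43-, 6.53-, 6.07- and 6.06-fold lower on their named probe sets. Other FOSL2, VDR and SMAD3 probe sets were not called and included positive differences of 0.41, 1.05 and 0.46, and the other ABCC3 and NAB2 probe sets read −1.86 and −1.39, also not called. PADI1 was 7.32-fold higher with v-Myb (adjusted p = 0.00559), SOBP 5.31-fold, KRTAP5-8 4.83-fold, the Src-family kinase gene FYN 3.77-fold, the tetraspanin gene CD53 3.61-fold, HSPA2 2.47-fold and the semaphorin gene SEMA3C 2.42-fold. YLPM1 was 6.26-fold higher on 1 probe set, with differences of −0.02 and −0.01 on the others, and the other FYN and SEMA3C probe sets read 2.63 and 1.08 without being called. The c-Myb signals of PADI1, SOBP, KRTAP5-8 and YLPM1, from 51.6 to 127, lay below the c-Myb arrays' medians of 176 and 180. CXCR4, a known Myb target, was not called between these forms, with a difference of 1.43 on its brightest probe set (adjusted p = 0.0625).

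Lists that were lower with v-Myb than with c-Myb included estrogen response, in which OLFM1 (−1.24, adjusted p = 0.0233), IGFBP4 (−1.08, adjusted p = 0.0144) and CELSR2 (−0.85, adjusted p = 0.033) were the 3 of 21 that fell, with 8 fallen adjusted over the list alone. Its adjusted p was 2.24e-05, or an adjusted p of 0.343 with an estimated correlation. Histones had a median of −0.70, with none of 9 fallen over all genes and 5 adjusted over the list alone (list adjusted p = 0.000516, or an adjusted p of 0.343 with an estimated correlation). Luminal epithelial markers had a median of −0.23, with none of 18 called over all genes and 4 fallen and 1 risen adjusted over the list alone. MUC1, an epithelial mucin gene, read −0.99 and ESR1, the estrogen receptor gene, −0.72, neither called (adjusted p = 0.0976 and 0.101), and the list's adjusted p was 0.00171, or an adjusted p of 0.373 with an estimated correlation. Hypoxia and glycolysis had a median of −0.23, with none of 18 fallen over all genes and 1 adjusted over the list alone (list adjusted p = 0.00171, or an adjusted p of 0.343 with an estimated correlation). Immediate early genes had a median of −0.40, with none of 13 fallen over all genes and 4 adjusted over the list alone (list adjusted p = 0.0163, or an adjusted p of 0.343 with an estimated correlation). EGR1 read −2.55 with an adjusted p of 0.182. Estrogen response, histones and hypoxia had also passed upward with c-Myb against control. That comparison used the same c-Myb arrays, so part of this agreement is built in.

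In total, limma called 110 probe sets between v-Myb and c-Myb, 24 higher with v-Myb and 86 lower, and groups did not overlap for 43.2% of probe sets against 33.3% by chance. With no intensity trend 1 was called, the other DHRS2 probe set (log2 −3.78, adjusted p = 0.0496). The excess of lower calls was gone without c-Myb replicate 1, with 25 higher and 26 lower, and the count was 17 without c-Myb replicate 2, 13 of them lower, 20 and 66 without v-Myb replicates 1 and 2, with 19 and 62 lower, and 69 and 68 without 3Mutc replicates 1 and 2, with 57 and 56 lower, DHRS2 alone of 16 named genes held in each leave-out, and the luminal, hypoxia and immediate early lists were lost without 1 array (adjusted p of 0.518 and 0.141 for luminal without c-Myb replicate 1 and v-Myb replicate 2, 0.147 for hypoxia without c-Myb replicate 1, and 0.136 for immediate early without v-Myb replicate 2).

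Between 3Mutc and c-Myb, the co-chaperone gene DNAJB1 read 11163 ± 768.1 with 3Mutc against 4807 ± 696 with c-Myb (2.33-fold higher, log2 1.22, SE 0.14, adjusted p = 0.00573). HSPH1 and HSP90AA1, which encode large chaperones, were 1.85- and 1.66-fold higher (adjusted p = 0.0382 and 0.0412), although 3 other HSP90AA1 probe sets were not called (0.22 to 0.51). PADI1 was 5.51-fold higher (adjusted p = 0.0385) and PNN, a splicing-related gene, 1.83-fold higher, with its other probe sets at −0.33 and −0.13. The c-Myb signal of PADI1, 83.2, lay below the c-Myb arrays' medians of 176 and 180. Lower with 3Mutc were GDF15, a stress-induced secreted factor (2464 ± 619.3 against 7422 ± 1612, 3.01-fold lower, adjusted p = 0.0124), CDKN1A (2.12-fold, adjusted p = 0.0347) and ISG20 (2.48-fold, adjusted p = 0.0382, with its other probe set at −1.48 and not called). The amino acid transporter gene SLC7A5 was 1.89-fold lower, and TRAPPC14 and PPDPF 3.79- and 2.23-fold lower.

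In the heat shock list 2 of 13 genes were higher with 3Mutc than with c-Myb, DNAJB1 and HSPH1, and 5 adjusted over the list alone. The list named 16 genes, and only these 13 had a probe set with 1 gene symbol. Its median was 0.37 and its adjusted p 7.46e-07, or an adjusted p of 0.385 with an estimated correlation. The NF-kB and TNF response list was lower, with a median of −0.42 over 10 genes, of which none passed over all genes or adjusted over the list alone. TNFAIP2, a gene induced by TNF, read −1.27 (adjusted p = 0.41), and the list's adjusted p was 0.0343, or an adjusted p of 0.554 with an estimated correlation. In total, limma called 18 probe sets, 9 in each direction, and groups did not overlap for 41.3% of probe sets against 33.3% by chance. Without the intensity trend limma called 0, with 1008 at an unadjusted p under 0.05 against 1184 with it, and in a fit of the compared groups alone it called 9 higher and 25 lower. None of the 11 named genes held in each leave-out, the count was 9 without either control array, 8, all higher, without c-Myb replicate 1, 8 without either v-Myb array, 1 without c-Myb replicate 2 (a probe set without a single gene symbol), 4 without 3Mutc replicate 1 (the same probe set, DNAJB1, GDF15 and BAIAP2) and 0 without 3Mutc replicate 2 (906 at an unadjusted p under 0.05), and the NF-kB list was lost without c-Myb replicate 1 or 3Mutc replicate 2 (adjusted p = 0.103 and 0.297), whereas the heat shock list was called in all 8.

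Between v-Myb and 3Mutc, DHRS2 was 12.8-fold lower with v-Myb (log2 −3.68, SE 0.28, adjusted p = 6.44e-05) and DNAJB1 was 3.00-fold lower (3713 ± 104.2 against 11163 ± 768.1, adjusted p = 0.000147). ABCC3, MT1H, SAT1 and the LIM-domain gene CSRP2 were 8.26-, 4.23-, 3.96- and 3.93-fold lower with v-Myb (2.73- and 6.54-fold for MT1H without v-Myb replicates 1 and 2), and SIPA1L3 and TNFRSF21 3.34- and 2.80-fold lower. FOSL1 was 5.24-fold higher with v-Myb (666 ± 1.7 against 121 ± 60.7, adjusted p = 0.0289), TRAPPC14 4.05-fold, MGAT2 2.74-fold, FABP5 2.40-fold and HSPA2 2.38-fold. BASP1, the chromatin reader gene BRD3 and PTTG1, which encodes securin of the mitotic checkpoint, were 1.98-, 1.94- and 1.78-fold higher. Other probe sets of MGAT2 (1.10), BRD3 (0.61), ABCC3 (−0.94), CSRP2 (−1.35), SIPA1L3 (−0.20) and TNFRSF21 (−0.83), and 1 of SAT1, were not called.

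The heat shock list was lower with v-Myb than with 3Mutc, with HSPB1 (−1.14, adjusted p = 0.00263) and DNAJB1 the 2 of 13 that fell and 10 fallen adjusted over the list alone. The median was −0.48 and the adjusted p 4.26e-12, or an adjusted p of 0.144 with an estimated correlation, and fry gave an adjusted p of 0.0286. Histones had a median of −0.78, with none of 9 fallen over all genes and 5 adjusted over the list alone (list adjusted p = 4.52e-06, or an adjusted p of 0.318 with an estimated correlation). Estrogen response had a median of −0.22, with none of 21 fallen over all genes or adjusted over the list alone (list adjusted p = 0.00158, or an adjusted p of 0.328 with an estimated correlation). Luminal epithelial markers had a median of −0.18, with none of 18 fallen over all genes and 3 adjusted over the list alone (list adjusted p = 0.00197, or an adjusted p of 0.340 with an estimated correlation). Hypoxia and glycolysis had a median of −0.30, with none of 18 fallen over all genes or adjusted over the list alone (list adjusted p = 0.00898, or an adjusted p of 0.340 with an estimated correlation). The 3Mutc and v-Myb arrays also served the other comparisons in which these lists passed, so these results are not independent of those. In total, limma called 33 probe sets, 11 higher with v-Myb and 22 lower (11 and 13 under quantile normalization), and groups did not overlap for 42.6% of probe sets against 33.3% by chance. Without the intensity trend limma called 0, with 1218 at an unadjusted p under 0.05 against 1422 with it. DHRS2 and DNAJB1 alone of 16 named genes held in each leave-out, the count was 13 and 14 without c-Myb replicates 1 and 2, with 10 and 11 lower, 12 and 13 without 3Mutc replicates 1 and 2 and 10 and 21, all of them lower, without v-Myb replicates 1 and 2, and the luminal and hypoxia lists were lost without v-Myb replicate 2 (adjusted p = 0.208 and 0.116).

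The remaining lists passed in none of the 6 comparisons. Among 16 measured known Myb targets, CXCR4 alone rose with v-Myb and none was called with c-Myb or 3Mutc against control. Adjusted over the list alone, 1 fell with c-Myb, 1 fell with 3Mutc, and 1 rose and 2 fell with v-Myb. The hematopoietic target MPO read −1.53 with c-Myb (adjusted p = 0.434) and the luminal factor gene GATA3 −0.62, −0.58 and −0.76 with c-Myb, 3Mutc and v-Myb, none called. CEBPB, a myeloid and epithelial transcription factor gene, was lower with v-Myb than with c-Myb (−0.96, adjusted p = 0.0313). The lowest camera adjusted p of the known Myb targets over the comparisons was 0.288. It was 0.0955 for G1/S and DNA replication, in which RRM2, a ribonucleotide reductase subunit, rose with c-Myb (0.76, adjusted p = 0.0233), and 0.0686 for the interferon response, in which ISG20 alone was called with c-Myb. It was 0.321 for the unfolded protein response, in which DNAJB9, a chaperone of the endoplasmic reticulum, rose with c-Myb (1.28, adjusted p = 0.00988), and 0.381 for cholesterol synthesis, in which INSIG1, a sterol sensor, rose with c-Myb (1.25, adjusted p = 0.0353). It was 0.457 for the BCL2 family, 0.729 for hematopoietic markers, 0.435 for basal and mesenchymal markers and 0.282 for housekeeping genes. TFRC, the transferrin receptor gene on the last list, rose with c-Myb (0.73, adjusted p = 0.0177), and VIM, a mesenchymal filament gene, read −2.01 without passing (adjusted p = 0.126). Of 108 list tests 21 passed at the preset correlation, camera passed 0 with an estimated correlation (7 at an unadjusted p under 0.05) and fry called 2. Median, mean and test differed in sign in 14 of these 108 tests, none of them called, among them p53 targets between v-Myb and c-Myb, with a median of 0.22 and a mean of −0.08.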

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

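The brightest probe set of each gene in place of the named one was tried after seeing the data, and the other alternatives were planned. With that probe set 104 of the 118 named gene results stayed called, 8 were lost and 6 changed direction without being called, because other probe sets were read. They were ACAA2 with c-Myb (−1.16) and 3Mutc (−0.78), YLPM1 with c-Myb (0.086), and YLPM1, FOSL2 and VDR between v-Myb and c-Myb (−0.017, 0.41 and 0.82). No named probe set changed direction under the other settings in which named genes were run, 96 of 118 being tested with a mean above the 60th percentile, and none of the 21 called lists did under the settings run for lists. Each named probe set had been chosen with both arrays of 1 group beyond both of the other. Leaving out an array or changing the pseudocount, filter, block, trend or fold threshold therefore could not reverse its direction. The calls themselves depended on how the spread was estimated and on single arrays, and where the fit tested other probe sets or held fewer arrays that construction is the difference, while for other settings the cause was not tested. With eBayes without the trend, limma called 2 probe sets for c-Myb, 1 for v-Myb and 0 for 3Mutc against control, 1 for v-Myb against c-Myb, 0 for 3Mutc against c-Myb and 0 for v-Myb against 3Mutc, and the shared counts were 0, 0 and 0. The counts at an unadjusted p under 0.05 were 1516, 1008 and 1218 for the comparisons without a call. Of the named results 2 stayed called and 116 did not.

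Without the filter on dim probe sets the counts were 151, 22 and 69 for c-Myb, v-Myb and 3Mutc against control, 61 for v-Myb against c-Myb, 5 for 3Mutc against c-Myb (DNAJB1, GDF15 and probe sets without a single gene symbol) and 14 for v-Myb against 3Mutc, with shared counts of 11, 41 and 9, and 52 named results stayed called. With a mean above the 60th percentile c-Myb and v-Myb shared 45 calls, 3 lists passed with c-Myb, and all 96 named results that were still tested stayed called. Quantile normalization left 8 calls for 3Mutc against c-Myb and kept 98 named results and 18 lists. At least 2-fold left 152, 75 and 67 calls for c-Myb and 3Mutc against control and v-Myb against c-Myb, and shared counts of 15, 34 and 12. With 1 probe set per gene the counts were 89 for v-Myb, 10 for 3Mutc against c-Myb and 53 shared by c-Myb and v-Myb. In fits of only the groups compared they were 95, 9 and 79 against control and 34 for 3Mutc against c-Myb, and 59 named results stayed called. camera with an estimated correlation passed 0 lists with c-Myb and 0 with 3Mutc, and with a mean of all probe sets of a gene 3 passed with c-Myb. The values as deposited and pseudocounts of 1 and 64 kept 117, 102 and 116 named results.

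With the replicate number as a block 1 list passed with v-Myb, luminal epithelial markers, downward (adjusted p = 0.0378), as it did without v-Myb replicate 1 (adjusted p = 0.044). The block kept 106 named results. Deviations from the group means correlated between −0.0247 and 0.0259 for arrays of the same number, so the numbers were not taken to pair the arrays.

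Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 44 to 226 calls for c-Myb, 13 to 79 for v-Myb and 18 to 146 for 3Mutc against control, 17 to 119 for v-Myb against c-Myb, 0 to 9 for 3Mutc against c-Myb (906 at an unadjusted limma p under 0.05 where 0) and 10 to 29 for v-Myb against 3Mutc. Shared counts were 4 to 55 for c-Myb and v-Myb, 9 to 95 for c-Myb and 3Mutc and 2 to 53 for 3Mutc and v-Myb, and lists passing against control 0 to 6, 0 to 1 and 2 to 5. Without control replicates 1 and 2, 76 and 66 named results stayed called, 43 and 33 without c-Myb replicates 1 and 2, 40 and 41 without 3Mutc replicates 1 and 2, and 63 and 61 without v-Myb replicates 1 and 2. Signal over background could not be judged without detection calls.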

Other observations

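Tests chosen only after the result was seen were the camera test of metallothioneins, the medians over 4 other stress lists, the count of probe sets higher with v-Myb than with c-Myb, the medians by signal class, and the shares of the rise judged by a left-out c-Myb array, and the metallothionein and NRF2 lists were also drawn up after gene values had been seen. With c-Myb 45 probe sets were called higher than with both control and v-Myb, a selection that itself used the v-Myb arrays, and no functional group was tested among them. EPHX1, an epoxide hydrolase, rose by 2.18 log2 units with c-Myb and 1.25 with 3Mutc and read 0.52 with v-Myb, and the glutathione transferase gene GSTM3 rose by 1.35 and 0.83 and read 0.59. SERPINA3, a secreted protease inhibitor of the acute phase response, rose by 1.85 with c-Myb and 1.28 with 3Mutc and read −0.17 with v-Myb (limma adjusted p = 1.81e-05, 0.000578 and 6.25e-06 for c-Myb and 3Mutc against control and v-Myb against c-Myb). OAT, which makes glutamate semialdehyde from ornithine, rose by 1.09 and 1.13 and read −0.02, and ASS1 of the urea cycle rose by 1.73 with c-Myb and read 0.43 and −0.14 without passing. The matrix protein gene TGFBI rose by 1.84 and 1.64 and read 0.65. Of the 45 probe sets, 19 were also called higher with 3Mutc than with control. The genes in this paragraph were picked after their values were seen.

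Metallothionein genes, which encode small metal-binding proteins, rose with c-Myb at 5 of 8 measured genes and with 3Mutc at 3, with list medians of 1.61 and 0.78. With c-Myb MT1H, MT1X, MT1HL1 and MT1F rose by 2.25, 2.20, 2.68 and 1.73 log2 units on their brightest probe sets, and MT2A rose too. The list was drawn up after large rises of its members had been seen and still holds them, so its camera p of 2.22e-09 (adjusted p = 0.0927 with an estimated correlation) restates those rises and is no independent test of the family. Many of these probe sets match several family members, and probe sets of 1 gene differed, at −0.35 and 1.41 for MT1E and 1.73 and 0.04 for MT1F, so single members are uncertain. A metal response is a hypothesis that was left undecided, since SLC30A1, a zinc exporter gene outside the family, read 0.51 (SE 0.363, adjusted p = 0.53). An NRF2 response, a hypothesis for the rises of CBR3, ABCC3 and EPHX1, was also left undecided. The other 13 NRF2 targets had a median of −0.18 (bootstrap interval −0.465 to 0.238) and a camera p of 0.971, while NQO1 among them rose by 1.11. The median and camera p met the levels planned as evidence against it. The bootstrap interval, which was not part of that plan, extended above the planned level.

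Of 13 heat shock genes 2 were called higher with 3Mutc than with c-Myb, or 5 adjusted over the list alone, with a list median of 0.37 and an adjusted p of 7.46e-07 that was lost with an estimated correlation (adjusted p = 0.385). The scaling between arrays is argued against as the cause, with a median of 0.349 under quantile normalization. So is a single array, with a lowest median of 0.259 over the 4 pairs of 3Mutc and c-Myb arrays. A general stress of the 3Mutc cultures that raises 4 other stress lists was not seen. Their genes had a median of −0.227 (bootstrap interval over genes −0.359 to −0.0395, 57 genes). Medians were −0.42 for NF-kB and TNF response, −0.31 for immediate early genes, −0.10 for p53 targets and −0.06 for unfolded protein response. The interval resamples genes and does not measure variation between cultures, so other forms of stress stay open. The handling of these cultures remains open and untested, as does a biological difference between the Myb forms.

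The 45 probe sets called higher with c-Myb than with both control and v-Myb may reflect a different activity of v-Myb. That is a hypothesis, since no Myb protein or transgene level was measured. Over all 197 higher calls of c-Myb against control, v-Myb replicates 1 and 2 reached median shares of 0.472 and 0.596 of the c-Myb rise. A partial rise could come with a weaker dose or a different activity, so these shares do not decide between them. The scaling between arrays is argued against by 36 of the 45 probe sets still called against v-Myb under quantile normalization. A weaker dose of the same activity stays open, since 3 probe sets, of PTTG1, HSPA2 and MORF4L1, were called higher with v-Myb than with both control and c-Myb, but limma called 0 such probe sets without v-Myb replicate 2 and 0 without the trend (101 and 173 at an unadjusted p under 0.05 in both comparisons), 5 without control replicate 1 (PPM1E, HSPA2, BASP1 and 2 of CXCR4), 5 without control replicate 2 (PPM1E, HSPA2, MORF4L1 and 2 of CXCR4), 2 without c-Myb replicate 2 (PTTG1 and MORF4L1), 1 without c-Myb replicate 1 (MORF4L1) and 1, HSPA2, without v-Myb replicate 1 or either 3Mutc array. The test of a weaker dose also took the median v-Myb minus c-Myb difference of the 3 CXCR4 probe sets, which was 1.53. That met the level set against a weaker dose, but CXCR4 was chosen after its rise with v-Myb had been seen. A v-Myb label on a c-Myb sample was left undecided by the planned test, in which a v-Myb array reached a median share of 0.596 of the c-Myb rise, between the levels set for and against it. In the later test the left-out c-Myb arrays reached 0.905 (bootstrap interval 0.841 to 0.948, 70 probe sets) and 0.937 (0.852 to 1.03, 40 probe sets) of the rise and the v-Myb arrays at most 0.411 (0.275 to 0.524), which argues against such a label.

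Of the 56 lower calls with c-Myb, 41 lay in the brightest of 3 signal classes, 9 in the middle and 6 in the dimmest. The scaling between arrays is argued against by 50 lower calls still made under quantile normalization. A shift of all dim probe sets on the control arrays was left undecided. Over the 3738 probe sets within the interquartile range of the lower calls' signal the median difference was 0.0195. Of these, 91.2% lay in the brightest class, so that median speaks against a shift only for bright probe sets. Over all probe sets of the dimmest and middle classes the medians were −0.19 (bootstrap interval −0.22 to −0.163) and −0.07. The lower calls there had medians of −2.39 and −1.42, but had been selected for passing the threshold, the weakest at −2.04 and −1.14. Their medians would lie below the class medians with or without a shift, so this comparison cannot decide it. A single control array stays open, since the 2 control arrays lay over 2-fold above both c-Myb arrays for 32.1% and 44.6% of the lower calls, which cannot decide it because the median lower call was itself under 2-fold. Lower calls numbered 18 without control replicate 1, 3 without control replicate 2 (HSPA9, PDLIM7 and PADI1), 42 without c-Myb replicate 1, 4 without c-Myb replicate 2 (PSG9, MIOS, AHCYL2 and a probe set without a single gene symbol), named after their values were seen, and 21 and 22 without 3Mutc replicates 1 and 2.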
